A study of Mus musculus with 18 samples.

How the data were processed

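RNA sequencing was carried out on 18 libraries of mouse KP pancreatic cancer cells lacking Atg7, which carried an empty vector or an Atg7 cDNA. The cells were untreated, treated with TNFα (100 ng/mL, 24 h) or grown as subcutaneous tumors, giving 6 groups of 3 libraries named by the labels. RNA was purified with a Qiagen RNeasy kit and libraries were made from 1 µg of total RNA, per the labels' protocols. Reads were processed with STAR 2.7, featureCounts 1.6 and DESeq2 1.20 under R 3.5.1 on the mm10 mouse genome, per the submitters' processing notes, which give the tools without their settings. Whether counting used the strand was not given in the sources used here, so antisense transcripts such as Bcas1os2 are uncertain, as are paralogs that share reads (Ly6, Gst, H2 and Prl2c genes).

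The deposited values are a signal per gene that is never negative, namely gene counts divided by a size factor per library, for 49030 genes. Dividing by the step worth 1 read gave whole reads for 100% of values (tolerance 0.001 read, largest deviation 0.00035 read), so the counts and size factors were recovered. Libraries held 17965118 to 20885105 recovered reads, with 13166 to 15925 genes at 10 reads or more, so counting error is small for all but low genes. Intervals and floors cover counting error only. All 49030 gene identifiers matched the GENCODE M21 annotation of GRCm38/mm10, and 48559 names were equal. No pair of replicates agreed within sampling noise, so each library counted as 1 sample.

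The deposited size factors had been set separately within 3 sets of 6 libraries (untreated culture, TNF-treated culture and tumors). Comparisons within a set, and differences between such comparisons, used the values as deposited. Comparisons across sets (TNF in either line, and tumors against untreated culture) used 1 added factor per set from median ratios of the recovered reads, which moved TNF-treated culture by 0.0786 and tumors by 0.203 log2 against untreated culture. This departs from the design written in advance, which foresaw dropping or marking such comparisons. Group means are printed on the deposited scale of their own set.

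Values were tested as log2(value + 1) with limma (trend), keeping genes at 10 or more in at least 3 of the fitted libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count test was not the main test because the deposited values are not counts. Culture comparisons were fitted on all 12 culture libraries, the tumor comparison on the 6 tumors, and the 2 comparisons of tumors with culture on those 6 and the 6 untreated cultures. Fold changes on the log2(value + 1) scale understate changes of low genes. Against a group without reads, a fold was computed against a floor of 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% exact interval.

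Gene lists, 36 in number, covered pathways and cell types. Lists with 5 or more tested members were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether members move on balance one way. The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule took Atg7, the 6 higher and 6 lower genes of largest log2 fold change with an adjusted p under 0.05, a mean of 100 or more in the higher group and replicates that did not overlap (5 each way and no overlap condition for differences of responses), leaving out predicted genes without a proper symbol. It added up to 4 members of smallest adjusted p from each list with 3 or more members called or with a camera call. The text keeps at most 2 members per list and at most 30 genes per comparison (20 for differences of responses), a limit set after values were seen, and 1 gene the rule took is not reported here. Ly6 genes in tumors, and autophagy genes, Mcpt2 and Ly6-region genes among the closing observations, were chosen after their values were seen.

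Same-numbered tumors deviated together from their group means, with correlations of 0.137, 0.222 and 0.374 in the 3 pairs. By the rule that each of at least 3 pairs must exceed 0.1, the numbers pair the tumor libraries. The labels give no reason for a pairing, so it comes from the data alone, and the main test was kept without the block.

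Alternatives were pseudocounts of 0.5 and 5, no filter, TMM scaling, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, the compared groups alone, all 18 libraries in 1 fit, a replicate block and leaving out each library. On recovered reads edgeR called 3030 genes in untreated culture, 3002 with TNF, 4410 and 3431 for TNF in vector and Atg7 cells, 186 for their difference, 904 in tumors, 12422 for tumors against culture and 711 for the dependence on growth. The deposited scale across sets was added after seeing the data. Each test was checked on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 90, 91, 90 and 88 of the former in the 4 main culture comparisons, 82 for the difference of TNF responses, 70 for tumors against culture, 3 in tumors and 2 for the dependence on growth. Of genes changed 2-fold it recovered 98, 96, 100, 98, 90, 98, 32 and 31 in the same order. The simulation gave all genes of a comparison 1 common dispersion, so these rates do not carry over to the real genes.

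Analyses ran under R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and under Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.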

Results

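Gene expression was measured by RNA sequencing in 18 libraries from mouse KP pancreatic cancer cells in which the autophagy gene Atg7 had been knocked out. The knockout cells carried either an empty vector (vector cells, without autophagy gene function) or an Atg7 cDNA (Atg7 cells, with the gene restored). Both lines were grown in culture without treatment, in culture with the inflammatory cytokine TNFα at 100 ng/mL for 24 h, or as subcutaneous tumors in C57BL/6J mice. These 6 groups held 3 libraries each, with 17965118 to 20885105 reads assigned to genes per library. Levels are deposited normalized read counts, given as mean ± SD (n = 3 per group), and log2 fold changes are given ± SE. Adjusted p-values of single genes are from limma with Benjamini-Hochberg adjustment, and those of gene lists are from camera. Replicates are not stated to be separate cultures or animals, so p-values measure only the spread between these libraries, and the vector and Atg7 lines may differ by more than Atg7.

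Atg7 (ENSMUSG00000030314, GRCm38/mm10, chromosome 6, 114643097 to 114860614, plus strand, protein coding), which encodes the E1-like enzyme of both autophagy conjugation systems, was read first as a check of the labels. Its normalized count in untreated culture was 374 ± 16.6 in vector cells and 175182 ± 5656 in Atg7 cells, 467-fold lower in vector cells (log2 fold change -8.87 ± 0.05, limma adjusted p = 6.41e-44). With TNF the counts were 329 ± 17.5 and 169430.0 ± 4638, 514-fold lower in vector cells (adjusted p = 4.04e-44, limma). In tumors they were 487 ± 25.4 and 84449 ± 5530.0, 173-fold lower (adjusted p = 5.84e-10, limma). All 9 vector libraries lay below all 9 Atg7 libraries, as their labels state. TNF did not change Atg7 past the threshold in either line, with log2 fold changes of -0.11 ± 0.05 in vector cells and 0.031 ± 0.05 in Atg7 cells, and a difference between these of -0.14 ± 0.07 (limma adjusted p = 0.484). In vector cells the change passed with the scales as deposited (-0.185, limma adjusted p = 0.00234) and without vector untreated replicate 3 (-0.143, limma adjusted p = 0.0322). Averaged over the lines, Atg7 changed by -0.14 ± 0.04 log2 from untreated culture to tumors (limma adjusted p = 0.01001). That average joined opposite moves, a higher level in tumors than in culture for vector cells and a lower one for Atg7 cells, as the means above give on separate deposited scales. The gap between the lines was smaller in tumors than in untreated culture by 1.43 ± 0.09 log2 (limma adjusted p = 9.22e-07). Tumors also held host RNA, which can narrow this gap without a change in the cancer cells.

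**Figure D1:**
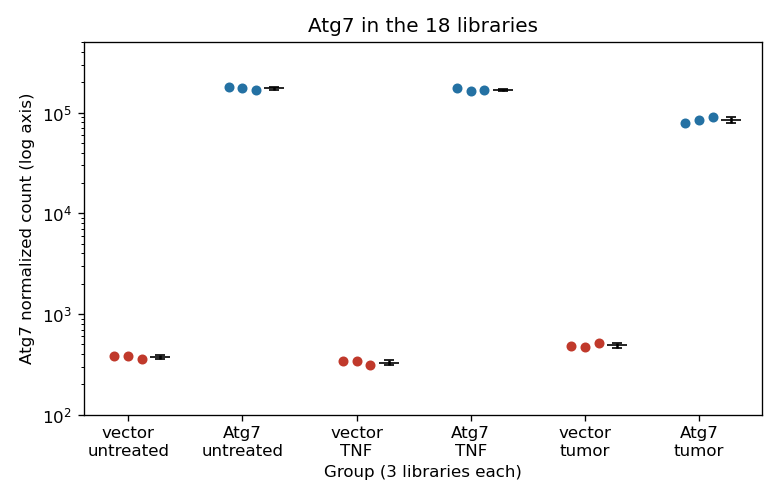
Atg7 normalized count (log axis) in each of the 18 libraries, as points by group, with the mean and SD of 3 libraries as a bar beside them. Vector groups averaged 329 to 487 and Atg7 groups 84449 to 175182.

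The libraries fell apart first by growth condition. The first principal component of the 18 libraries held 97.0% of the variance and parted tumors from culture, and the second held 0.90%. Within the 12 culture libraries, with the genes most variable there, the first 2 components held 47.5% and 34.7%. Mitochondrially encoded genes took 1.53% to 2.12% of reads in culture and 4.03% to 4.97% in tumors. In the third replicate of the Atg7 tumors, 26.9% of reads lay in genes that overlap ribosomal RNA, against 0.29% to 0.71% in the other 17 libraries.

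The first comparison asked how untreated vector cells differed from untreated Atg7 cells. In untreated culture, vector cells had far higher levels of Ly6e, Ly6a and Ly6c1, genes of the Ly6 cluster that encode GPI-anchored surface proteins. Ly6e (ENSMUSG00000022587, chromosome 15, 74955051 to 74959905, plus strand, protein coding) stood at 3709.6 ± 247 in vector cells and 69.9 ± 26.5 in Atg7 cells (log2 fold change 5.79 ± 0.17, limma adjusted p = 1.91e-22). Ly6a, known as the stem cell antigen Sca-1, stood at 698 ± 39.3 against 29.5 ± 3.94 (4.52 ± 0.13), and Ly6c1 at 421 ± 63.2 against 9.92 ± 5.07 (5.38 ± 0.24). Psen2, a catalytic subunit of gamma-secretase, was higher by 4.2 ± 0.36, the lipid transporter gene Abca13 by 4.07 ± 0.42 and the actin-binding neurabin gene Ppp1r9a by 3.74 ± 0.36. Cbx7, a subunit of the Polycomb repressive complex, was 59.4-fold lower in vector cells, at 1.67 ± 1.57 against 135 ± 12.3 (limma adjusted p = 3.18e-13). Isyna1, the enzyme that makes inositol phosphate from glucose 6-phosphate, was 8.22-fold lower (78.9 ± 8.95 against 654 ± 32.3). The transcription factor gene Ets1 was 6.901-fold lower, Nhsl1 6.87-fold lower and the collagen gene Col8a1 6.69-fold lower. For each of these genes the 3 libraries of one line all lay above the 3 of the other.

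Targets of the stress-response factor ATF4, which serves amino acid supply, had the lowest camera p of the lists tested in untreated cells. Of its 28 tested members, 25 were higher and 3 did not pass (26 higher adjusted over the list alone). Their median was 0.49, with camera adjusted p = 3.15e-21 (0.1203 with an estimated correlation). Cth, which makes cysteine from cystathionine, stood at 2761 ± 490.0 against 1209 ± 158, and the stress transcription factor gene Atf5 at 1053 ± 129 against 478 ± 41.6. Among 25 genes of cholesterol synthesis, 1 was higher, 14 were lower and 10 did not pass (1 higher and 17 lower adjusted over the list alone). Their median was -0.19, with camera adjusted p = 2.74e-06 (0.1203 with an estimated correlation). Hmgcs1, an early enzyme of the mevalonate route, changed by -0.32 ± 0.05 and Acat2 by -0.43 ± 0.06. Of 15 epithelial genes, 2 were higher, 9 were lower and 4 did not pass (2 higher and 10 lower adjusted over the list alone). Their median was -0.33, with camera adjusted p = 5.29e-06 (0.1203 with an estimated correlation). Keratin genes were among the lower ones, Krt7 at 8780.2 ± 624 against 23445 ± 649 and Krt8 1.79-fold lower. Of 35 cell cycle genes, 10 were lower and 25 did not pass (12 lower adjusted over the list alone). Their median was -0.083, with camera adjusted p = 0.001598 (0.614 with an estimated correlation). The mitotic kinesin gene Kif20a changed by -0.25 ± 0.05 and the replication helicase gene Mcm7 by -0.22 ± 0.05.

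Of 18 genes of the endoplasmic reticulum (ER) stress response, 6 were higher and 12 did not pass (7 higher adjusted over the list alone). Their median was 0.10, with camera adjusted p = 0.00853 (0.1203 with an estimated correlation). The higher members included Xbp1, its transcription factor, by 0.31 ± 0.05 and the co-chaperone gene Dnajc3 by 0.28 ± 0.05. Of 29 hypoxia and glycolysis genes, 10 were higher, 2 were lower and 17 did not pass (10 higher and 2 lower adjusted over the list alone). Their median was 0.10, with camera adjusted p = 0.00853 (0.438 with an estimated correlation). Bnip3, a mitophagy receptor induced by hypoxia, stood at 541 ± 45.8 against 169 ± 22.1, and the ER oxidase gene Ero1l was higher by 0.54 ± 0.06. Of 13 mesenchymal transition genes, 3 were higher, 5 were lower and 5 did not pass (3 higher and 6 lower adjusted over the list alone), and the matricellular growth factor gene Ccn2 was 2.76-fold lower while the receptor kinase gene Axl changed by -0.61 ± 0.05. Their median was -0.10, with camera adjusted p = 0.0263 (0.1203 with an estimated correlation). The list of autophagy machinery held 4 higher and 5 lower genes among 42 (4 and 6 adjusted over the list alone). Its median was 0.043, its mean -0.20 and its test pointed down (camera adjusted p = 0.788). That list holds Atg7 itself, the gene set apart by design, which counts among the lower genes and pulls the mean down. The NF-kB targets, genes switched on by TNF signalling, held 8 higher and 10 lower genes among 34 (9 and 13 adjusted over the list alone), with a median of -0.12, a mean of 0.057 and a downward test (camera adjusted p = 0.863).

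In all, limma called 2942 of 13816 tested genes at an adjusted p under 0.05 in untreated culture, 1372 higher and 1570 lower in vector cells, of which 446 differed at least 2-fold. No list call of untreated culture held with an estimated correlation between members. The mesenchymal call was lost with no filter, and it and the hypoxia call with all 18 libraries in 1 fit.

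The second comparison asked the same of cells treated with TNF. Here too the Ly6 genes were higher in vector cells, Ly6e at 4527 ± 374 against 62.6 ± 13.4 and Ly6a at 1046 ± 75.8 against 55.5 ± 9.77, with Ly6c1 higher by 4.9 ± 0.24. Abca13 had the largest difference among the genes named by size, 308 ± 54.9 against 3.57 ± 3.77 (log2 fold change 6.54 ± 0.42, limma adjusted p = 6.85e-14). The Notch ligand gene Dll1 stood at 261 ± 22.1 against 9.53 ± 2.84 and Ppp1r9a was higher by 4.02 ± 0.36. Proliferin genes were lower in vector cells, Prl2c3 21.5-fold (6.55 ± 1.65 against 159 ± 12.8) and Prl2c2 11.6-fold. The calcium-binding protein gene S100a7a was 13.5-fold lower, Cbx7 22.95-fold and Col8a1 11.1-fold. Again the 3 libraries of one line lay apart from the 3 of the other for each of these genes.

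Some genes of inflammation and antigen presentation were higher in TNF-treated vector cells. Of 34 NF-kB targets, 14 were higher, 3 were lower and 17 did not pass (15 higher and 3 lower adjusted over the list alone). The median of NF-kB targets was 0.15, with camera adjusted p = 2.31e-04 (0.0877 with an estimated correlation). The chemokine gene Ccl20, which attracts cells that carry CCR6, stood at 6995 ± 204 against 2555 ± 180.3, and the leukocyte adhesion gene Vcam1 at 5253 ± 451 against 1387 ± 74.5. Of 15 genes induced by interferon gamma, 9 were higher and 6 did not pass (10 higher adjusted over the list alone). The median of interferon gamma genes was 1.29, with camera adjusted p = 7.78e-06 (0.0109 with an estimated correlation). Irf1, a transcription factor of that response, stood at 2379.7 ± 77.04 against 1781 ± 148, and the guanylate-binding protein gene Gbp9 at 83.7 ± 22.9 against 10.03 ± 3.42. Of 18 genes of MHC class I presentation, 10 were higher, 1 was lower and 7 did not pass (10 higher and 1 lower adjusted over the list alone). The median of MHC class I genes was 0.20, with camera adjusted p = 2.03e-04 (0.0545 with an estimated correlation). The class I heavy chain gene H2-D1 was higher by 0.41 ± 0.05, and Erap1, which trims peptides in the ER, stood at 975 ± 51.5 against 619 ± 40.9. Of 21 type I interferon-stimulated genes, 8 were higher and 13 did not pass (8 higher adjusted over the list alone), among them Parp14 by 1.02 ± 0.15 and Ifi27 by 0.59 ± 0.11. The median of type I interferon genes was 0.40, with camera adjusted p = 0.00837 (0.249 with an estimated correlation). Of 8 endothelial genes, 5 were higher, 1 was lower and 2 did not pass (5 higher and 1 lower adjusted over the list alone). The median of endothelial genes was 0.33, with camera adjusted p = 0.00615 (0.0545 with an estimated correlation). Cdh5, which encodes VE-cadherin, stood at 294 ± 6.04 against 39.2 ± 3.702. Tek, the angiopoietin receptor gene, had 59 reads in vector and 3 in Atg7 cells, a ratio of 18.9 with a 95% counting interval of 6.17 to 94.4.

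Several further lists that differed in untreated cells differed again. Of 18 ER stress genes, 11 were higher and 7 did not pass (15 higher adjusted over the list alone), among them Dnajc3 by 0.45 ± 0.05 and the chaperone gene Hyou1 by 0.38 ± 0.05. The median of ER stress genes was 0.18, with camera adjusted p = 4.56e-07 (0.0109 with an estimated correlation). Of 25 cholesterol synthesis genes, 1 was higher, 16 were lower and 8 did not pass (2 higher and 18 lower adjusted over the list alone). The median of cholesterol genes was -0.24, with camera adjusted p = 1.77e-06 (0.0545 with an estimated correlation). Pmvk, which acts on mevalonate phosphate, stood at 1044 ± 47.8 against 1733 ± 47.7 and Hmgcs1 changed by -0.38 ± 0.05. Of 28 ATF4 targets, 16 were higher, 1 was lower and 11 did not pass (19 higher and 2 lower adjusted over the list alone), including the asparagine synthetase gene Asns by 0.45 ± 0.06 and the stanniocalcin gene Stc2 by 0.46 ± 0.06. The median of ATF4 targets was 0.23, with camera adjusted p = 6.59e-06 (0.379 with an estimated correlation). Of 15 epithelial genes, 2 were higher, 8 were lower and 5 did not pass (2 higher and 10 lower adjusted over the list alone), with Krt7 changed by -1.18 ± 0.05 and Krt8 by -0.76 ± 0.04. The median of epithelial genes was -0.41, with camera adjusted p = 6.59e-06 (0.0545 with an estimated correlation). In all, 2980 of 13816 genes passed with limma under TNF, 1407 higher and 1573 lower in vector cells, and 526 differed at least 2-fold. With an estimated correlation, only the ER stress and interferon gamma calls held here.

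Across 13816 genes, the difference between the lines without TNF and that with TNF, which share no library, had a Pearson correlation of 0.75 and a Spearman correlation of 0.56. Genes are not independent replicates. Of the genes called in both, 822 were higher in vector cells in both settings (139.7 expected of independent lists), 985 were lower in both (179 expected) and 16 went opposite ways.

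The next comparisons asked how each line answered TNF. In vector cells, Vcam1 went from 28.1 ± 1.45 to 5253 ± 451, 189.9-fold up (log2 fold change 7.57 ± 0.16, limma adjusted p = 2.73e-26). The macrophage growth factor gene Csf1 rose from 117 ± 18.2 to 2232 ± 154, Tnip3, an inhibitor of NF-kB signalling, from 23.4 ± 4.31 to 931 ± 45.5, and the collagenase gene Mmp13 from 19.7 ± 10.6 to 389 ± 42.1. The complement protease gene C1s1 rose by 4.88 ± 0.53 and the phosphodiesterase gene Gdpd5 by 4.31 ± 0.13. Among genes that fell, the selenium-binding protein gene Selenbp1 went from 2283 ± 133 to 189 ± 38.8, 11.6-fold down, and the cytochrome P450 gene Cyp2s1 from 5431 ± 277 to 638 ± 27.9, 8.05-fold down. Mettl7b fell 17.6-fold, Adm, which encodes the vasodilator adrenomedullin, 9.74-fold, the microvillus gene Vil1 8.44-fold and the inflammasome sensor gene Nlrp6 7.34-fold. Levels with and without TNF lie on separate deposited scales, while the fold changes were taken after bringing the sets to 1 scale.

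In Atg7 cells, Vcam1 rose 129-fold, from 10.9 ± 4.61 to 1387 ± 74.5 (log2 fold change 7.01 ± 0.16, limma adjusted p = 2.63e-25), and Ccl20 from 189 ± 23.3 to 2555 ± 180.3. Tnip3 rose by 4.49 ± 0.19, Prl2c2 by 3.91 ± 0.32, Gdpd5 by 3.67 ± 0.13 and Csf1 by 3.43 ± 0.10. Mucin genes were among those that fell. The gel-forming mucin gene Muc5ac went from 1875 ± 199 to 161 ± 9.31, 10.9-fold down, Muc5b fell 9.44-fold, the membrane mucin gene Muc4 7.39-fold and Mucl3 6.92-fold. Gkn2, a gastric mucosa gene, fell 7.68-fold and Mettl7b 6.702-fold.

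By list, NF-kB targets rose in both lines. In vector cells, of 34 members, 32 rose and 2 did not pass (32 higher adjusted over the list alone), with Nfkbia, the inhibitor that closes the NF-kB loop, up by 3.47 ± 0.07 and Ccl20 by 3.86 ± 0.08. The median of NF-kB targets there was 1.73, with camera adjusted p = 2.87e-41 (3.17e-04 with an estimated correlation). In Atg7 cells, 28 rose and 6 did not pass (31 higher adjusted over the list alone), with Nfkbia up by 3.11 ± 0.07 and the neutrophil chemokine gene Cxcl5 by 3.21 ± 0.09. The median was 1.5, with camera adjusted p = 1.50e-43 (2.58e-04 with an estimated correlation). Of 18 MHC class I genes, 16 rose and 2 did not pass (16 higher adjusted over the list alone) in vector cells. The median of MHC class I genes there was 0.99, with camera adjusted p = 1.23e-15 (0.00107 with an estimated correlation). In Atg7 cells 14 rose and 4 did not pass (15 higher adjusted over the list alone). The median was 0.68, with camera adjusted p = 2.03e-12 (0.00215 with an estimated correlation). The peptide-loading gene Tapbp rose by 2.05 ± 0.08 in vector and 1.53 ± 0.08 in Atg7 cells, and the light chain gene B2m by 0.98 ± 0.05 and 0.73 ± 0.05. Of 16 interferon gamma genes, 11 rose and 5 did not pass (12 higher adjusted over the list alone) in vector cells, with Irf1 up by 1.52 ± 0.06. The median of interferon gamma genes there was 1.43, with camera adjusted p = 1.52e-06 (0.00393 with an estimated correlation). In Atg7 cells 7 rose and 9 did not pass (9 higher adjusted over the list alone), with Irf1 up by 1.17 ± 0.06 and the MHC class II chaperone gene Cd74 from 1.98 ± 1.01 to 25.1 ± 4.06. The median was 1.16, with camera adjusted p = 9.84e-05 (0.0122 with an estimated correlation). The interferon chemokine gene Cxcl10 in vector cells went from 1.72 ± 2.98, near the floor, to 58.3 ± 9.28.

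ATF4 targets, cholesterol synthesis and hypoxia genes fell with TNF. Of 28 ATF4 targets, 26 fell and 2 did not pass (1 higher and 26 lower adjusted over the list alone) in vector cells. The median of ATF4 targets there was -0.90, with camera adjusted p = 4.86e-28 (0.0329 with an estimated correlation). Cth fell 3.46-fold and the glycine transporter gene Slc6a9 2.75-fold. In Atg7 cells 1 rose, 26 fell and 1 did not pass (1 higher and 26 lower adjusted over the list alone). The median was -0.62, with camera adjusted p = 1.94e-23 (0.04601 with an estimated correlation). Trib3, a pseudokinase of this response, fell 2.76-fold there and Slc6a9 changed by -1.04 ± 0.08. Of 25 cholesterol synthesis genes, 24 fell and 1 did not pass (24 lower adjusted over the list alone) in vector cells, with Pmvk at -1.0 ± 0.05 and the lanosterol demethylase gene Cyp51 at -0.85 ± 0.05. The median of cholesterol genes there was -0.44, with camera adjusted p = 2.07e-18 (0.00393 with an estimated correlation). In Atg7 cells 23 fell and 2 did not pass (24 lower adjusted over the list alone), with Cyp51 at -0.74 ± 0.05 and the lanosterol synthase gene Lss at -0.85 ± 0.06. The median was -0.53, with camera adjusted p = 1.08e-23 (0.00215 with an estimated correlation). Of 29 hypoxia and glycolysis genes, 2 rose, 24 fell and 3 did not pass (2 higher and 25 lower adjusted over the list alone) in vector cells, Ero1l 4.04-fold and the aldolase gene Aldoc 4.08-fold. The median of hypoxia genes there was -0.42, with camera adjusted p = 1.88e-16 (0.0108 with an estimated correlation). In Atg7 cells 1 rose, 20 fell and 8 did not pass (2 higher and 24 lower adjusted over the list alone), Ero1l 2.27-fold and Aldoc 2.38-fold. The median was -0.34, with camera adjusted p = 3.19e-13 (0.0204 with an estimated correlation).

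Smaller shifts were seen in other lists. Of 18 ER stress genes, 13 rose, 1 fell and 4 did not pass (13 higher and 1 lower adjusted over the list alone) in vector cells, with the disulfide isomerase gene Pdia6 up by 0.50 ± 0.04 and Manf by 0.52 ± 0.05 (median log2 fold change 0.24, camera adjusted p = 8.05e-06, adjusted p = 0.00685 with an estimated correlation), and in Atg7 cells 8 rose, 1 fell and 9 did not pass (8 higher and 1 lower adjusted over the list alone). The median was 0.13, with camera adjusted p = 0.00261 (0.0397 with an estimated correlation). Of 35 cell cycle genes, 19 rose, 2 fell and 14 did not pass (19 higher and 2 lower adjusted over the list alone) in vector cells, with the replication helicase genes Mcm4 up by 0.54 ± 0.05 and Mcm2 by 0.40 ± 0.05. The median of cell cycle genes there was 0.14, with camera adjusted p = 1.30e-05 (0.314 with an estimated correlation). In Atg7 cells 16 rose, 1 fell and 18 did not pass (19 higher and 1 lower adjusted over the list alone), with Mcm2 up by 0.36 ± 0.05 and Mcm3 by 0.34 ± 0.05. The median was 0.12, with camera adjusted p = 2.52e-06 (0.262 with an estimated correlation). Of 29 NRF2 targets in Atg7 cells, 3 rose, 13 fell and 13 did not pass (5 higher and 13 lower adjusted over the list alone), with the glutathione transferase genes Gsta4 changed by -0.62 ± 0.04 and Gstm1 by -0.71 ± 0.05. The median was -0.15, with camera adjusted p = 5.06e-04 (0.0755 with an estimated correlation). In vector cells 7 NRF2 targets rose and 13 fell (7 and 14 adjusted over the list alone), with a median of -0.11 and camera adjusted p = 0.0486, which was lost in 4 alternatives. Of 8 endothelial genes in Atg7 cells, 5 fell and 3 did not pass (6 lower adjusted over the list alone). The median was -0.70, with camera adjusted p = 5.06e-04 (0.0192 with an estimated correlation). In vector cells 3 fell (4 adjusted over the list alone), with a median of -0.67 and camera adjusted p = 0.0219, which was lost in 3 alternatives. In Atg7 cells Tek went from 79 reads to 3, a ratio of 24.2 with a 95% counting interval of 7.99 to 119.9. Genes of TNF receptor signalling had 18 members up and 3 down of 40 in vector cells (18 and 3 adjusted over the list alone; median log2 fold change 0.10, camera adjusted p = 7.29e-05, adjusted p = 0.00561 with an estimated correlation). In Atg7 cells 11 rose, 1 fell and 28 did not pass (11 higher and 1 lower adjusted over the list alone). The median was 0.078, with camera adjusted p = 6.85e-04 (0.01295 with an estimated correlation). This median turned to just under 0 with the scales as deposited.

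Limma called 4344 of 13848 genes in vector cells, 2114 up and 2230 down with TNF, and 3387 of 13848 in Atg7 cells, 1613 up and 1774 down. At least 2-fold changes numbered 662 and 458. With each set on its own deposited scale, an alternative chosen after seeing the data, the calls were 4742 (1356 up, 3386 down) in vector and 3946 (987 up, 2959 down) in Atg7 cells. The list calls of this pair of comparisons held with an estimated correlation, apart from the cell cycle and NRF2 lists, and the endothelial list in vector cells, among those named here.

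A further comparison asked whether the lines differed in their response to TNF, by a test of the difference itself (response of vector cells minus that of Atg7 cells). Mmp13 rose from 19.7 ± 10.6 to 389 ± 42.1 in vector cells and from 40.01 ± 7.37 to 121 ± 23.4 in Atg7 cells, a difference of 2.82 ± 0.38 log2 (limma adjusted p = 2.92e-05). The NF-kB inhibitor gene Nfkbie reached 456 ± 47.2 from 27.8 ± 14.1 in vector cells and 153 ± 18.7 from 30.2 ± 6.47 in Atg7 cells (1.77 ± 0.32). The response was also more positive in vector cells for Abca13 (2.46 ± 0.59), the retinoic acid hydroxylase gene Cyp26b1 (1.53 ± 0.36), which fell less there, and the heme-binding protein gene Hpx (1.35 ± 0.24). Cyp2s1 fell more in vector cells, from 5431 ± 277 to 638 ± 27.9, than in Atg7 cells, from 6989 ± 175 to 2061 ± 355 (-1.31 ± 0.10, limma adjusted p = 7.69e-10). Selenbp1 (-1.47 ± 0.19), Adm (-1.76 ± 0.27), the serpin gene Serpinb9b (-1.75 ± 0.43) and the antisense transcript Bcas1os2 (-1.42 ± 0.36) also fell more in vector cells.

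Several lists answered TNF more in vector cells. Of 29 hypoxia genes, 7 were lower and 22 did not pass (10 lower adjusted over the list alone) in their response, with Ero1l at -0.83 ± 0.08 and Aldoc at -0.78 ± 0.12. Over these hypoxia genes the median difference was -0.093, with camera adjusted p = 1.63e-11 (0.0348 with an estimated correlation). Of 28 ATF4 targets, 8 were lower and 20 did not pass (15 lower adjusted over the list alone), with Cth at -0.91 ± 0.15 and the stress-induced regulator gene Nupr1 at -0.43 ± 0.10. Over these ATF4 targets the median difference was -0.27, with camera adjusted p = 2.12e-15 (0.138 with an estimated correlation). Of 34 NF-kB targets, 5 were higher, 1 was lower and 28 did not pass (10 higher and 1 lower adjusted over the list alone), with Csf1 at 0.91 ± 0.14 and Cxcl5 at 0.70 ± 0.13. Over these NF-kB targets the median difference was 0.25, with camera adjusted p = 1.76e-09 (0.0289 with an estimated correlation). Of 18 MHC class I genes, 2 were higher and 16 did not pass (6 higher adjusted over the list alone), with Tapbp at 0.52 ± 0.12 and Erap1 at 0.51 ± 0.12. Over these MHC class I genes the median difference was 0.31, with camera adjusted p = 6.66e-09 (0.0158 with an estimated correlation). Of 15 interferon gamma genes, 1 was higher and 14 did not pass (4 higher adjusted over the list alone), Irf1 at 0.36 ± 0.09 being the one over all genes. Over these interferon gamma genes the median difference was 0.36, with camera adjusted p = 0.00183 (0.0341 with an estimated correlation). The ER stress list was called with no single member past the threshold with limma, edgeR or DESeq2, or with limma adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 2.02e-04, adjusted p = 0.0313 with an estimated correlation). At an unadjusted p under 0.05, limma had 7 of its 18 members with a more positive and 1 with a less positive response.

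Limma called 170 of 13816 genes for this difference, 77 with a higher and 93 with a lower response in vector cells, against 1402 at an unadjusted p under 0.05. The count was 84 with no filter on low values and 17 with all 18 libraries in 1 fit, where Selenbp1 and Cyp2s1 kept their calls and the other genes named for this difference lost theirs. It was 84 without vector untreated replicate 2, 96 without vector TNF replicate 2, 104 without vector TNF replicate 3 and 110 without Atg7 TNF replicate 1. The lists named here held with an estimated correlation, apart from ATF4. Over 13848 genes, the TNF responses of the lines, which share no library, had a Pearson correlation of 0.77 (0.461 with no filter on low values) and a Spearman correlation of 0.66. Of genes called in both, 1222 rose in both lines (246 expected of independent lists), 1371 fell in both (286 expected) and 4 went opposite ways.

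**Figure D2:**
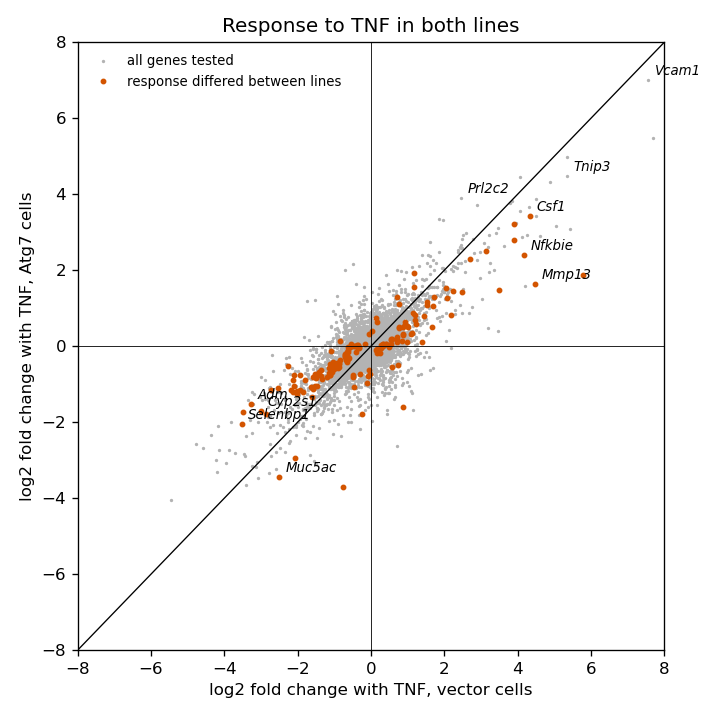
Log2 fold change with TNF in vector cells (horizontal axis) and in Atg7 cells (vertical axis), 1 point per tested gene, with the line of equal response; orange points are the 170 genes whose responses differed. Across the 5134 genes called in either line the slope was 0.72, and Vcam1 lay farthest up, at 7.57 and 7.01.

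The tumor comparison asked how the transcriptomes of vector and Atg7 tumors in mice differed, host cells included. The chemokine gene Ccl20 stood at 794 ± 14.7 in vector and 134 ± 30.7 in Atg7 tumors (log2 fold change 2.58 ± 0.16, limma adjusted p = 5.55e-04). The glutathione transferase gene Gstm1 stood at 9056 ± 745 against 2462 ± 517, and the aldehyde dehydrogenase gene Aldh3a1 at 5229 ± 624 against 1929 ± 112. Gsta3 (131 ± 116 against 4.001 ± 1.86), Gdf10 of the BMP family (108 ± 60.4 against 7.17 ± 5.48), the imprinted RNA gene H19 (453 ± 446 against 25.8 ± 5.81), Ly6m (3.46 ± 0.51), the tight junction gene Cldn1 (3.25 ± 0.61) and Tspan11 (3.08 ± 0.53) were also higher, with wide spread between vector tumors. Rbp4, a retinol carrier gene, was 6.16-fold lower in vector tumors (97.8 ± 44.2 against 566 ± 18.5), the endocytic receptor gene Cubn 4.301-fold lower, Isyna1 4.03-fold lower (135 ± 14.4 against 547 ± 51.6), Ankrd37 3.77-fold lower and Lrp2bp 4.46-fold lower. In these genes the 3 tumors of one line all lay above the 3 of the other. Ly6e was also higher in vector tumors, by 2.57 log2 (limma adjusted p = 1.95e-05), with Ly6c1 at 2.16 and Ly6a at 1.74.

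Most hypoxia and cholesterol synthesis genes were lower in vector tumors. Of 30 hypoxia and glycolysis genes, 17 were lower and 13 did not pass (22 lower adjusted over the list alone), among them the glycolytic enzyme genes Tpi1 at -0.84 ± 0.08 and Gpi1 at -0.62 ± 0.07. The hypoxia median was -0.64, with camera adjusted p = 3.25e-17 (0.625 with an estimated correlation). Of 25 cholesterol synthesis genes, 18 were lower and 7 did not pass (23 lower adjusted over the list alone), with Lss at -0.87 ± 0.12 and Pmvk at -0.89 ± 0.13. The cholesterol median was -0.54, with camera adjusted p = 2.65e-16 (0.625 with an estimated correlation). Of 35 cell cycle genes, 5 were lower and 30 did not pass (8 lower adjusted over the list alone), with the kinetochore genes Cenpe at -0.55 ± 0.06 and Cenpf at -0.67 ± 0.09. The cell cycle median was -0.24, with camera adjusted p = 4.37e-09 (0.641 with an estimated correlation). Markers of fibroblasts and endothelial cells, and some of macrophages, moved the other way between the same tumors, 1 of which was the Atg7 library rich in ribosomal RNA. Of 20 fibroblast genes, 10 were higher and 10 did not pass (15 higher adjusted over the list alone), among them C1s1 (799 ± 187 against 259 ± 34.5) and the complement inhibitor gene Serping1 (1882 ± 506 against 675 ± 63.4; median log2 fold change 1.27, camera adjusted p = 7.35e-11, adjusted p = 0.625 with an estimated correlation). Of 16 endothelial genes, 9 were higher and 7 did not pass (14 higher and 1 lower adjusted over the list alone), with Cdh5 at 3159 ± 227 against 1428 ± 219 and Tek higher by 1.37 ± 0.15. The endothelial median was 0.71, with camera adjusted p = 1.42e-08 (0.625 with an estimated correlation). C1s1, Cdh5 and Tek also had reads in TNF-treated vector cells, so they may not mark host cells. Of 24 macrophage and monocyte genes, 3 were higher and 21 did not pass (16 higher adjusted over the list alone), with the apolipoprotein gene Apoe at 7712 ± 1820.0 against 3601 ± 24.98 and Ms4a7 higher by 1.07 ± 0.23. The macrophage median was 0.75, with camera adjusted p = 3.39e-08 (0.641 with an estimated correlation).

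Some members of other lists were higher in vector tumors, alongside those host markers. Of 30 NRF2 targets, genes of the oxidative stress response, 12 were higher, 1 was lower and 17 did not pass (14 higher and 1 lower adjusted over the list alone); Aldh3a1 and Gstm1 above are members. For NRF2 targets in tumors the median was 0.44, with camera adjusted p = 8.27e-09 (0.625 with an estimated correlation). Of 44 NF-kB targets, 4 were higher and 40 did not pass (8 higher adjusted over the list alone), with Ccl20 above and the neutrophil chemokine gene Cxcl1 at 0.97 ± 0.21. For NF-kB targets in tumors the median was 0.30, with camera adjusted p = 2.31e-05 (0.677 with an estimated correlation). Of 34 lysosome genes, 3 were higher, 1 was lower and 30 did not pass (3 higher and 1 lower adjusted over the list alone), with Cd63 at 0.44 ± 0.08 and the hexosaminidase gene Hexa at 0.53 ± 0.11. The lysosome median was 0.14, with camera adjusted p = 0.00217 (0.719 with an estimated correlation). T cell genes had no member called in 21 tested with limma (also adjusted over the list alone), edgeR or DESeq2, and 1 higher at an unadjusted limma p under 0.05, with a median of 0.27 (camera adjusted p = 0.501). Interferon gamma genes had likewise no call in 26 with any of these tools and 1 higher at an unadjusted p under 0.05, with a median of -0.009, a mean of 0.022 and camera adjusted p = 0.635. Of 23 MHC class I genes, limma and edgeR called none and DESeq2 called 2 lower, the count limma had at an unadjusted p under 0.05; their median was 0.055 (camera adjusted p = 0.854). With the replicate number as a block, limma called 4 interferon gamma genes higher and 1 lower (6 and 1 adjusted over the list alone) and 1 MHC class I gene higher (6 higher and 2 lower adjusted over the list alone). Neither list was called by camera there (adjusted p = 0.923 and 0.289).

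Limma called 990 of 15612 genes between the tumors, 619 higher and 371 lower in vector tumors, with 383 at least 2-fold, against 3815 at an unadjusted p under 0.05. With the replicate number as a block, since same-numbered tumors deviated together, the count was 1514 (885 higher, 629 lower). Members called higher then numbered 15 of 20 for fibroblasts, 11 of 16 for endothelial cells, 9 of 24 for macrophages and 8 of 44 for NF-kB targets (18, 14, 17 and 14 adjusted over the list alone). With it 6 of 35 cell cycle genes were lower (8 adjusted over the list alone). Under the block, the iron and heme list gained a call (camera adjusted p = 0.0371, against 0.0619 without it, where 3 of its 29 genes were higher and 1 lower, and 4 higher and 2 lower adjusted over the list alone). That call did not hold with an estimated correlation (adjusted p = 0.695). The count was 593 without vector tumor replicate 1, 296 without vector replicate 2, 1594 without vector replicate 3, 330 without Atg7 replicate 1, 82 without Atg7 replicate 2 and 249 without Atg7 replicate 3, the library rich in ribosomal RNA. With DESeq2 on recovered reads it was 1833 (1077 higher, 756 lower), and with all 18 libraries in 1 fit 2978 (1238 higher, 1740 lower). No list call of the tumors held with an estimated correlation, while fry, which tests whether a list's genes move on balance one way, gave adjusted p-values of 0.0246 for hypoxia, 0.0406 for cholesterol synthesis and 0.0246 for endothelial genes. Under the block these 3 fry calls were lost, at an adjusted p of 0.165 each.

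**Figure D3:**
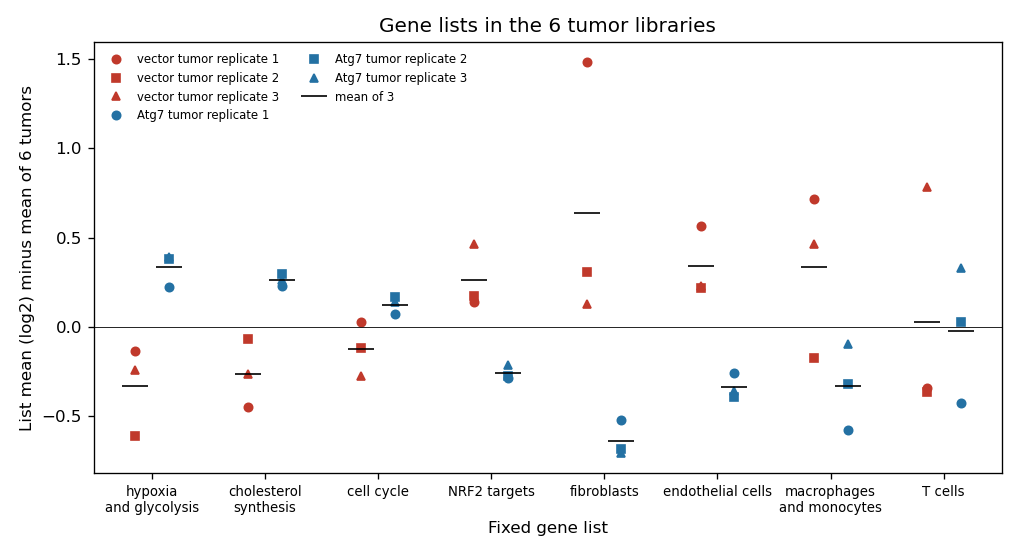
Mean log2 level of 8 gene lists in each of the 6 tumor libraries, minus the mean of the 6 tumors (vertical axis, log2), with vector tumors in red, Atg7 tumors in blue and the mean of 3 as a black line. The third Atg7 tumor replicate is the library with 26.9% of reads in genes overlapping ribosomal RNA.

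**Figure D4:**
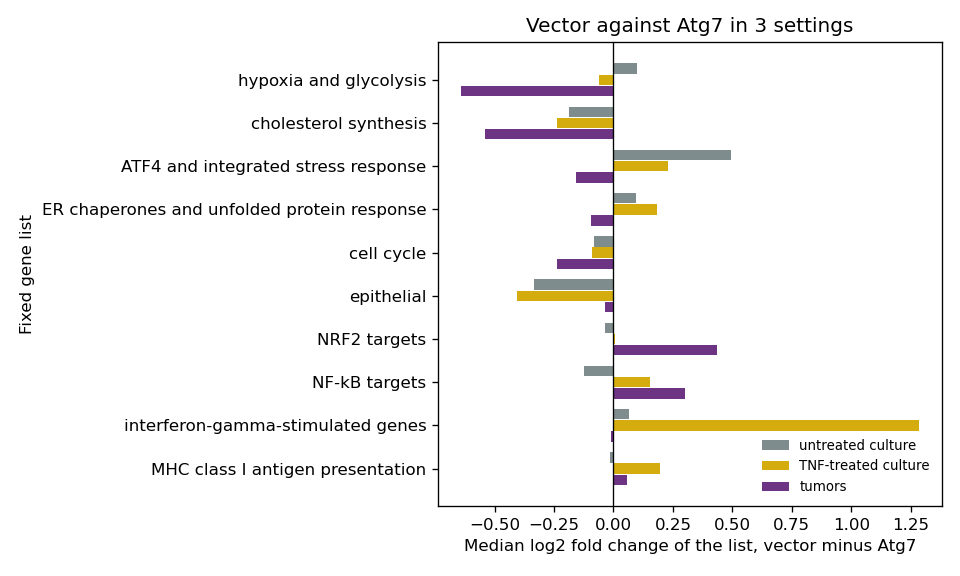
Median log2 fold change of 10 gene lists, vector minus Atg7 (horizontal axis), as 1 bar each for untreated culture, TNF-treated culture and tumors. The hypoxia list stood at 0.10 in untreated culture, -0.063 with TNF and -0.64 in tumors.

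The growth comparison set the 6 tumors against the 6 untreated cultures, to show what growth in a mouse adds. Genes of stroma and immune cells without any read in culture were abundant in tumors. Against a floor of 3 reads over the 6 culture libraries, the fibrillar collagen gene Col3a1 was at least 41171-fold higher in tumors and Col1a2 at least 28281-fold. Postn, a matrix gene of fibroblasts, was at least 8411-fold higher, the complement gene C1qa of macrophages at least 5261-fold and the MHC class II gene H2-Ab1 at least 5339-fold. Serping1 was at least 3028-fold higher, H2-Eb1 at least 2945-fold and the VEGF receptor gene Kdr at least 1299-fold. Fn1, which encodes fibronectin, had 3 reads in culture, a ratio of 26939 with a 95% counting interval of 9218 to 130630. Col3a1 stood at 26063 ± 18750.0 in vector and 8644 ± 1521 in Atg7 tumors. Col1a1 was higher by 11.67 ± 0.34 and the macrophage protease gene Ctss by 11.26 ± 0.30, on the log2 scale with a pseudocount. Among genes lower in tumors were the water channel gene Aqp5 (-4.98 ± 0.40), the germline small-RNA factor gene Gtsf1 (18.8-fold), the proton pump subunit gene Atp6v1c2 (18.4-fold), Crisp1 (17.7-fold), Fam71f1 (14.2-fold) and the adenylate kinase gene Ak5 (14.1-fold).

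Whole lists of host cell types rose with these genes. Of 20 fibroblast genes, 19 were higher and 1 was lower (19 higher and 1 lower adjusted over the list alone). As a list, fibroblast genes had a median of 9.52, with camera adjusted p = 2.14e-08 (0.233 with an estimated correlation). Of 24 macrophage and monocyte genes, 23 were higher and 1 was lower (23 higher and 1 lower adjusted over the list alone), with Apoe up by 6.1 ± 0.10. As a list, macrophage genes had a median of 7.61, with camera adjusted p = 8.50e-09 (0.233 with an estimated correlation). Of 16 endothelial genes, 15 were higher and 1 was lower (15 higher and 1 lower adjusted over the list alone), with the basement membrane collagen gene Col15a1 up by 9.72 ± 0.17. As a list, endothelial genes had a median of 5.49, with camera adjusted p = 6.08e-06 (0.114 with an estimated correlation). Of 21 T cell genes, 18 were higher and 3 did not pass (18 higher adjusted over the list alone). As a list, T cell genes had a median of 4.09, with camera adjusted p = 8.02e-04 (0.406 with an estimated correlation). With genes lacking reads in culture set to their bounds, the medians were 9.52 for fibroblasts, 8.08 for macrophages and 5.66 for endothelial cells. Of 32 type I interferon-stimulated genes, 32 were higher (32 higher adjusted over the list alone), with the RNA-sensing enzyme gene Oas3 up by 7.37 ± 0.13. As a list, type I interferon genes had a median of 6.1, with camera adjusted p = 1.39e-12 (0.192 with an estimated correlation). The nuclear body gene Sp100 went from 6.098 ± 2.23 in vector and 0 in Atg7 culture to 1829 ± 391.5 and 1438 ± 129. Of 26 interferon gamma genes, 26 were higher (26 higher adjusted over the list alone). As a list, interferon gamma genes had a median of 7.14, with camera adjusted p = 3.02e-08 (0.269 with an estimated correlation). Of 23 MHC class I genes, 20 were higher, 2 were lower and 1 did not pass (20 higher and 2 lower adjusted over the list alone). As a list, MHC class I genes had a median of 2.68, with camera adjusted p = 1.10e-05 (0.269 with an estimated correlation).

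Most cell cycle, ribosomal protein and ATF4 target genes were lower in tumors, where host markers rose. Medians are also given relative to that of all tested genes, 0.11. Of 38 ribosomal protein genes, 38 were lower (38 lower adjusted over the list alone), with Rps2 at -1.06 ± 0.04. As a list, ribosomal protein genes had a median of -0.58 (-0.70 relative to all genes), with camera adjusted p = 1.89e-14 (0.219 with an estimated correlation). Of 35 cell cycle genes, 33 were lower and 2 did not pass (33 lower adjusted over the list alone), with the checkpoint kinase gene Bub1 at -1.38 ± 0.06. As a list, cell cycle genes had a median of -0.87 (-0.98 relative to all genes), with camera adjusted p = 3.13e-12 (0.245 with an estimated correlation). Of 28 ATF4 targets, 1 was higher, 24 were lower and 3 did not pass (2 higher and 24 lower adjusted over the list alone), with the serine synthesis gene Psat1 6.702-fold lower and the mitochondrial serine hydroxymethyltransferase gene Shmt2 3.43-fold lower. As a list, ATF4 targets had a median of -1.68 (-1.79 relative to all genes), with camera adjusted p = 2.28e-09 (0.233 with an estimated correlation). Of 40 nuclear oxidative phosphorylation genes, 35 were lower and 5 did not pass (35 lower adjusted over the list alone), with the ATP synthase gene Atp5b at -0.80 ± 0.04. As a list, oxidative phosphorylation genes had a median of -0.40 (-0.51 relative to all genes), with camera adjusted p = 2.28e-09 (0.219 with an estimated correlation). Of 30 hypoxia and glycolysis genes, 5 were higher, 24 were lower and 1 did not pass (5 higher and 24 lower adjusted over the list alone). As a list, hypoxia genes had a median of -0.90 (-1.01 relative to all genes), with camera adjusted p = 8.63e-06 (0.269 with an estimated correlation). Of 19 epithelial genes, 18 were higher and 1 did not pass (18 higher adjusted over the list alone). As a list, epithelial genes had a median of 1.24 (1.13 relative to all genes), with camera adjusted p = 1.42e-05 (0.08897 with an estimated correlation).

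Limma called 12479 of 16156 genes between tumors and culture, 7203 higher and 5276 lower in tumors, and 4753 differed at least 2-fold. With the sets on their deposited scales the count was 12795 (5824 higher, 6971 lower) and the median of all genes moved from 0.11 to -0.09. No list call of this comparison held with an estimated correlation.

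The last comparison asked whether the difference between the lines depended on growth condition (vector minus Atg7 in tumors, minus the same in untreated culture). Host RNA in the tumors can narrow or widen such a gap without a change in the cancer cells. Aldh3a1 stood at 4678 ± 306 in vector and 5584 ± 156 in Atg7 culture, and at 5229 ± 624 and 1929 ± 112 in tumors, a difference of 1.69 ± 0.11 (limma adjusted p = 2.31e-06). Ly6e differed less in tumors (9649 ± 513 against 1631 ± 208) than in culture, by -3.22 ± 0.30. The gap in Cbx7 also shrank, with 1.67 ± 1.57 against 135 ± 12.3 in culture and 37.9 ± 15.7 against 137 ± 30.6 in tumors (4.01 ± 0.62). The spermine oxidase gene Smox went from 2.04 ± 1.07 against 37.4 ± 7.38 to 148 ± 52.7 against 125 ± 37.3 (3.92 ± 0.49), and the hedgehog effector gene Gli1 from 3.41 ± 5.103 against 8.89 ± 3.63 to 149 ± 61.3 against 29.5 ± 11.6 (4.08 ± 0.95). The pseudokinase gene Fam20a (-3.63 ± 0.48) and the guidance ligand gene Slit3 (-3.58 ± 0.32) went the other way. So did the G protein regulator gene Rgs2 (-3.23 ± 0.35) and the GTPase gene Gbp6 (-3.81 ± 0.75). The collagen VI genes Col6a1 (5.2 ± 0.58) and Col6a2 (3.8 ± 0.52) and the collagen gene Col15a1 (2.91 ± 0.34) stood higher in vector tumors but at or below 26.2 normalized reads in culture. For genes this low in culture, Slit3, Gbp6 and Fam20a included, the log2 value depends on the pseudocount, and the collagens are products of host fibroblasts too.

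Of 30 hypoxia genes, 22 were lower and 8 did not pass (1 higher and 24 lower adjusted over the list alone) in this difference, with Gpi1 at -0.77 ± 0.08 and Ankrd37 at -2.16 ± 0.26. The list median was -0.74, with camera adjusted p = 6.52e-21 (0.1898 with an estimated correlation). Of 28 ATF4 targets, 14 were lower and 14 did not pass (21 lower adjusted over the list alone), with Cth at -1.35 ± 0.21 and the glutamine transporter gene Slc1a5 at -0.77 ± 0.12. The list median was -0.61, with camera adjusted p = 1.09e-13 (0.196 with an estimated correlation). Of 30 NRF2 targets, 12 were higher and 18 did not pass (18 higher adjusted over the list alone), with Gstm1 at 1.24 ± 0.17 beside Aldh3a1. The list median was 0.49, with camera adjusted p = 1.60e-13 (0.195 with an estimated correlation). Of 25 cholesterol synthesis genes, 6 were lower and 19 did not pass (13 lower adjusted over the list alone), with Lss at -0.81 ± 0.14. The list median was -0.26, with camera adjusted p = 1.85e-07 (0.405 with an estimated correlation). Of 18 ER stress genes, 7 were lower and 11 did not pass (10 lower adjusted over the list alone). The list median was -0.28, with camera adjusted p = 1.50e-06 (0.195 with an estimated correlation). Fibroblast markers were called as a list too, 3 of 20 being higher (10 adjusted over the list alone; median log2 fold change 1.38, camera adjusted p = 1.89e-07, adjusted p = 0.369 with an estimated correlation).

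Limma called 991 of 16097 genes for this difference, 465 higher and 526 lower. With edgeR the count was 711 (413 higher, 298 lower) and with TMM scaling 936 (523 higher, 413 lower), so the balance of directions moved with the scaling. It was 1511 (679 higher, 832 lower) with all 18 libraries in 1 fit, 551 without vector untreated replicate 1, 642 without vector untreated replicate 2, 618 without vector untreated replicate 3, 656 without Atg7 untreated replicate 1, 573 without Atg7 untreated replicate 3, 1520 without vector tumor replicate 3 and 570 without Atg7 tumor replicate 2. None of the list calls held with an estimated correlation. Across 13244 genes, the vector effects in untreated culture and in tumors, which share no library, had a Pearson correlation of 0.38 (0.175 with no filter on low values) and a Spearman correlation of 0.25. Of genes called in both, 153 were higher in vector cells in both (32.2 expected of independent lists), 158 lower in both (42.6 expected) and 36 opposite.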

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

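These results are listed because a test of a difference between 2 groups' effects passed its threshold. Weighed here are 3 patterns between the lines. The comparisons among host cell types, of epithelial with hypoxia genes, of the Ly6a to Ly6e ratio in cultured cells and of the genes flanking Ly6e were tests chosen after the result was seen.

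The response to TNF differed between vector and Atg7 cells for 170 genes. More positive responses in vector cells were those of Mmp13 (2.82 log2), Abca13 (2.46), Nfkbie (1.77), Cyp26b1 (1.53), Hpx (1.35), Csf1 (0.91), Cxcl5 (0.70), Tapbp (0.52), Erap1 (0.51) and Irf1 (0.36). More negative ones were those of Adm (-1.76), Serpinb9b (-1.75), Selenbp1 (-1.47), Bcas1os2 (-1.42), Cyp2s1 (-1.31), Cth (-0.91), Ero1l (-0.83), Aldoc (-0.78) and Nupr1 (-0.43). Median differences of lists were -0.27 for ATF4 targets, -0.093 for hypoxia, 0.25 for NF-kB targets, 0.31 for MHC class I, 0.12 for ER stress, 0.36 for interferon gamma genes, -0.067 for ribosomal proteins, 0.052 for TNF receptor signalling and 0.16 for type I interferon genes. With an estimated correlation the calls of ATF4 targets, ribosomal proteins and type I interferon genes did not hold.

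The difference between the lines depended on growth condition for 991 genes, where the tumors also held RNA of host cells. It was higher in tumors than in culture for Atg7 (1.43), Col6a1 (5.2), Gli1 (4.08), Cbx7 (4.01), Smox (3.92), Col6a2 (3.8), Col15a1 (2.91), Aldh3a1 (1.69) and Gstm1 (1.24). It was lower for Gbp6 (-3.81), Fam20a (-3.63), Slit3 (-3.58), Rgs2 (-3.23), Ly6e (-3.22), Ankrd37 (-2.16), Cth (-1.35), Lss (-0.81), Gpi1 (-0.77) and Slc1a5 (-0.77). List medians were -0.74 for hypoxia, -0.61 for ATF4 targets, 0.49 for NRF2 targets, -0.26 for cholesterol synthesis, -0.28 for ER stress, 0.29 for epithelial genes, 0.35 for NF-kB targets, 0.15 for lysosome, -0.12 for cell cycle and 0.45 for mesenchymal genes. Those of cell types were 1.38 for fibroblasts, 0.74 for macrophages, 1.01 for adipocytes, 0.73 for dendritic cells and 0.75 for endothelial cells. None of these list calls held with an estimated correlation. The endothelial call was also lost in 10 alternatives, the dendritic in 5, the mesenchymal in 3, the macrophage in 2 and the fibroblast and cell cycle calls in 1 each.

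As lists, fibroblast and endothelial markers were higher in vector than in Atg7 tumors, with 10 of 20 and 9 of 16 members called. Neither list call held with an estimated correlation (adjusted p = 0.625 each), and the endothelial fry call was lost under the replicate block (0.165). A lower share of cancer cells in vector tumors would raise markers of all host cells alike. Fibroblast minus pericyte markers differed by 0.996 ± 0.46 log2 (SE), just beyond 2 SE. With 3 tumors per line a margin of 2 SE is too narrow to decide, so a lower share of cancer cells stays open. The difference rests on few samples, since it was 0.577 ± 0.257 without vector tumor replicate 1 and within 2 SE on leaving out any 1 of 3 other tumors. Fibroblast minus T cell markers differed by 1.23 ± 0.77 without pairing, which leaves that share open too. With same-numbered tumors paired the SE was 0.452 and the difference lay beyond 2 SE, but 3 pairs are too few for that margin to decide. It lay within 2 SE without the first or the second pair. Paired, the pericyte comparison had an SE of 0.465 and lay within 2 SE without the second or the third pair. Without the Atg7 tumor rich in ribosomal RNA the fibroblast median was 1.26 against 1.27, which argues against that library as the cause. A biological effect of the Atg7 state of the cancer cells on the stroma may remain as a hypothesis, untested here.

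As a list, hypoxia and glycolysis genes were lower in vector tumors, with 17 of 30 members called. The list call did not hold with an estimated correlation (adjusted p = 0.625), and the fry call was lost under the replicate block (0.165). Fewer cancer cells would lower epithelial genes too, but epithelial minus hypoxia genes differed by 0.688 ± 0.18 (SE; 0.214 paired). Paired, it lay within 2 SE without the third pair (0.671 ± 0.370). Yet epithelial genes rose from culture to tumors, so the test cannot decide. Without the library rich in ribosomal RNA the hypoxia median was -0.62 against -0.64. Effects of the genotype on blood supply or cancer cells may apply too, untested here.

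Ly6e, Ly6a and Ly6c1 were higher in cultured vector cells and in whole vector tumors. In tumors host cells may contribute, as endothelial and fibroblast markers were higher too. If all Ly6a reads were Ly6e reads, the Ly6a to Ly6e ratio would be constant. Over the 3 vector groups it ranged by 0.308 log2 (pooled SD 0.259), which leaves this open. In cultured vector cells it rose with TNF by 0.296 (SD 0.057), which argues against that. A part may still be, as Ly6a rose with TNF in Atg7 cells too. A gain of the whole region would raise its neighbours, yet the 27 tested genes outside the Ly6 family within 1 Mb (chromosome 15, 73955051 to 76272235) had a median of 0.231, with 8 higher and none lower, which argues against a gain as the cause of a difference this large. A change in regulation, with or without Atg7, may account for it, untested here.

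Other splits of the libraries were also fitted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split was 1 of 10 in each of the 5 such comparisons. It called 2942 genes in untreated culture, 2980 with TNF, 4344 and 3387 for TNF in vector and Atg7 cells and 990 in tumors, and the highest other split called 0 in each, by limma. Among the tumors, 4 of the 10 splits part all 3 same-numbered pairs, and the 3 besides the real one called 0. For the difference of TNF responses 5 of 100 drawn splits called as many genes (170 real, 503 at most). For the dependence on growth 2 of 100 did (991 real, 2811 at most). The splits with 503 and 2811 exchange genotype labels of 4 and 6 libraries and so carry the genotype difference itself. Neither share measures chance, which was not excluded. For tumors against culture 1 of 100 did (12479 real, 6716 at most), but host RNA alone could give this.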

How the results depend on the processing

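The deposited scale across sets and its values were chosen after seeing the data; the other settings were planned. Of the 688 results for named genes, 549 kept their direction and side of the threshold under every alternative run, as did 127 of 167 list results, lists by their camera direction. No gene call and no camera direction reversed, but the medians of 4 called lists changed sign. These were macrophage genes for TNF in either line, TNF receptor signalling for TNF in Atg7 cells and type I interferon genes for the difference of TNF responses. For the difference of TNF responses this held for 3 of 30 genes and 7 of 10 lists, and in tumors for 16 of 63 genes and 9 of 17 lists. Leaving aside left-out libraries, 154 gene and 50 list values lost a call and 1 and 14 gained one; among left-out libraries 420 and 46 lost and 1 and 8 gained one. Where a library is left out, fewer samples are fitted and the remaining pair is assumed to vary like the other groups. In other settings the cause was not tested.

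The difference of TNF responses had 84 genes (39 higher, 45 lower) with no filter, of which 80 were among the 170 and more genes were tested, and 17 (9 and 8) with all 18 libraries in 1 fit, of which 15 were. The tumor count was 1833 (1077 and 756) with DESeq2, including 989 of the 990, and 2978 (1238 and 1740) with all 18 libraries. The dependence on growth had 1511 genes (679 and 832) with all 18 libraries. The correlation of TNF responses was 0.774, and 0.768 with a pseudocount of 0.5, 0.799 with 5 and 0.461 with no filter; that of vector effects in culture and tumors was 0.385, and 0.175 with no filter.

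Without each library in turn, the TNF correlation ranged from 0.748 to 0.769 and that of vector effects from 0.334 to 0.395. The difference of TNF responses ranged from 84 genes (without vector untreated replicate 2) to 159, with 96 and 104 without vector TNF replicates 2 and 3 and 110 without Atg7 TNF replicate 1. The dependence on growth ranged from 551 (without vector untreated replicate 1) to 1520 (without vector tumor replicate 3), with 642 and 618 without vector untreated replicates 2 and 3, 656 and 573 without Atg7 untreated replicates 1 and 3 and 570 without Atg7 tumor replicate 2. The tumor count ranged from 82 (without Atg7 replicate 2) to 1594 (without vector replicate 3), with 593 and 296 without vector replicates 1 and 2 and 330 and 249 without Atg7 replicates 1 and 3. The other counts ranged from 2306 to 2800 in untreated culture, 2321 to 2777 with TNF, 3543 to 3927 and 2733 to 3252 for TNF in vector and Atg7 cells, and 12153 to 12388 for growth.

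With the replicate number as a block, which was taken to pair the tumor libraries, the tumor count was 1514 (885 and 629), including 950 of the 990. Under the block Zc3h12a lost its call (limma adjusted p 0.0522 against 0.0478, log2 fold change 0.44 without it) and the iron and heme list gained one by camera (adjusted p 0.0371 against 0.0619, and 0.695 with an estimated correlation). No other limma call of a named tumor gene or camera call of a list changed, while the fry calls of hypoxia, cholesterol synthesis and endothelial genes were lost (adjusted p 0.165 each). The numbers do not pair culture libraries with each other or with tumors. Same-numbered pairs correlated from -0.23 to 0.31 (median -0.02, 18 pairs) in culture and from -0.12 to 0.35 (median -0.01) in untreated culture with tumors. There the 3 pairs of tumors alone exceeded 0.1 (0.209, 0.145 and 0.349), but these are the same tumor libraries as before. In these fits the block, which joins all libraries of a number, gave 2813 and 2882 genes between the lines without and with TNF, 4247 and 3285 for TNF in vector and Atg7 cells, 165 for their difference, 12463 for growth and 903 for its dependence on genotype. Depth limits genes with few reads, such as Col6a1, Gbp6 and Slit3 in culture.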

Other observations

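The genes in this part were chosen after their values were seen. Among genes of autophagy itself, Gabarapl1, an ATG8-family gene, was lower in vector cells without TNF (509.7 ± 21.6 against 1086 ± 70.05, limma adjusted p = 1.06e-13) and with TNF (545 ± 25.03 against 962 ± 21.8, limma adjusted p = 7.13e-11), while it stood at 476 ± 10.7 in vector and 515 ± 55.00 in Atg7 tumors. The autophagy receptor gene Sqstm1, whose protein is degraded by autophagy, stood at 5249 ± 388 in vector and 5439 ± 107 in Atg7 cells in untreated culture without a call, and was lower in vector cells with TNF (3874 ± 95.3 against 5101 ± 329.7, limma adjusted p = 4.88e-07). Map1lc3b, which encodes the ATG8 protein LC3B, stood at 1379.6 ± 56.4 in vector and 1395 ± 41.9 in Atg7 cells in untreated culture and at 1621 ± 66.3 in vector and 1537 ± 54.1 in Atg7 tumors, without a call.

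The mast cell protease gene Mcpt2 stood at 52.9 ± 2.97 in vector and 156 ± 13.2 in Atg7 cells in untreated culture and at 4539 ± 231 in vector and 6550.0 ± 570.3 in Atg7 tumors, and of all tested genes it had the lowest p in the comparison of tumors with culture (6.09 ± 0.06, limma adjusted p = 2.04e-17). It was lower in the vector than in the Atg7 group in untreated culture, with TNF and in tumors, by limma (-1.54 ± 0.27, -2.48 ± 0.27 and -0.53 ± 0.08). It belongs to a family of similar genes that can share reads, so its values are uncertain. Among other genes of the Ly6 region, Ly6f was higher in the vector group by 2.18, 2.23 and 2.15 log2 in untreated culture, TNF-treated culture and tumors, and Ly6g2 by 2.16, 2.01 and 1.97. Not all did so. Psca stood at -0.831 and -1.699 in untreated and TNF-treated culture (limma adjusted p = 0.400 and 0.0502), and Slurp1 in culture and Ly6c2 and Gpihbp1 in tumors were not called.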
